A study of Drosophila melanogaster with 3 samples.

How the data were processed

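Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out, per the labels, on whole Drosophila melanogaster embryos of both sexes aged 0 to 24 h. The flies carried a transgene for CG10209 fused at its C-terminus to green fluorescent protein (GFP), and an antibody against GFP was used. The series holds 1 group of 3 biological replicates, numbered as the labels number them, with no second condition. Per the labels, chromatin was broken by sonication to a size range of 200 to 800 bp. No mock precipitation, untagged line or expression measurement was used here.

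The authors deposited region lists in narrowPeak layout with dm6 and with dm3 coordinates. Per the text files deposited with the lists, regions were called separately for each replicate and once for the pooled replicates, against 1 control alignment common to all of them. Each region list is limited to 30000 regions and so holds background regions as well. A further list holds the peaks the authors kept by the irreproducible discovery rate (IDR), which compares the ranks of regions between replicates. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The authors' signal value of each region spans different ranges in the replicate lists and the pooled list, so it mainly served to describe or rank regions within 1 list. Values were compared directly between lists only for IDR peaks against pooled regions, whose values the IDR peaks carry, and for dm6 against dm3 peaks. The deposited −log10 q of each region was used to count regions at 2 or more, a q of 0.01. The lists give no read counts, so read depth per sample is unknown. Intervals are exact binomial 95% intervals and cover counting error only.

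Positions were taken from the dm6 lists. The reference was Release 6 of the genome with the Ensembl 115 annotation on X, 2L, 2R, 3L, 3R, 4 and Y, without transposable elements: 18277 genes, 13968 of them protein coding. All regions lay on these arms and 0 ran past the end of an arm. Coordinates are 1-based dm6 positions. A promoter peak has its summit within 500 bp of an annotated transcription start, and counts for each gene with a start in that range. Promoter share was compared with 100000 random placements of the summits on the same arms, for which the smallest p is 1e-05. Arms were tested with exact binomial tests against their share of sequence without N bases. Gene lists, 26 in number, were tested with Fisher's exact test against other genes of the same biotype, and 18 consensus motifs with exact McNemar tests of the 100 bp either side of a summit against a window centred 1000 bp to its right. Words of 8 bases were found in odd-ranked peaks, and the best 10 were tested in even-ranked peaks. All these tests but that of the promoter share, which was one-sided, were two-sided, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. The tRNA, snoRNA and snRNA lists departed from the design: fewer than 50 other genes of their biotype exist, so they were not tested within it, and were instead set against all other genes that are not protein coding, a background chosen after seeing the data. Symbols nos, calypso and SmG matched no annotated gene.

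Replicates were compared by the share of IDR peaks that a region among the 6307 of highest signal overlapped by at least 1 bp, 6307 being the number of IDR peaks, and by Spearman's correlation of signal values over peaks. Peak numbers were compared between builds without converting coordinates. Tests, lists, motifs and alternatives were fixed before the data were examined, except where a choice made after seeing the data is named as such. Genes named are CG10209, the genes nearest the 20 highest peaks outside CG10209, and for each list up to 4 members with the highest promoter peaks, or up to 2 by alphabet where none has one. Alternatives were the 3153 peaks of highest signal, other windows, flanks, backgrounds and overlaps, omission of each replicate and omission of peaks within 20 kb of CG10209. Leaving out a replicate kept the IDR peaks that a top-ranked region of both others overlapped, because IDR itself was not rerun. Alternatives with dm3 peaks that need a dm3 genome were not run.

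The tests of promoter share, gene lists, motifs and words, and the overlap of regions, were tested on simulated data. Of 50 sets of 6307 random peaks, 1 had a promoter p under 0.05. Of 100 simulated lists of 80 genes bound at 60%, 100 passed, as did 9 of 400 lists of 80 at the base rate, in runs on 13968 genes. Most lists tested here are smaller, so these runs do not show how often a small list would pass. Simulated genes were bound independently, whereas neighbouring genes can share a peak. A planted motif and a planted word were recovered in 3000 simulated windows, with 0 other motifs and 0 other words past the threshold. Simulated centres and flanks had the same base composition, whereas A and T made up 64.3% of bases at real summits and 57.8% in flanks. The simulation therefore cannot show false calls that arise from composition. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.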

Results

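The genomic sites occupied by GFP-tagged CG10209 were mapped by ChIP-seq in 0 to 24 h Drosophila embryos in 3 biological replicates. The IDR list held 6307 peaks in dm6, with a median width of 444 bp and signal values from 194.7 to 15205 (median 341). They lay on 6263 distinct intervals, so some peaks share an interval. The 30000 pooled regions, background included, had the same median width, so width does not set the peaks apart from background. All signal values are the authors' own, and all 6307 IDR peaks are regions of the pooled list. The lowest peak has a signal of 194.682, and pooled regions outside the peaks with a −log10 q of 2 or more reach 194.667. A single peak need not recur in each replicate: 45 peaks overlapped none of the top 6307 regions of any replicate. At a −log10 q of 2 or more, replicate 1 had 4296 regions, replicate 2 had 9183 and replicate 3 had 9015. With 1 group and no second condition, the genome served as the reference, and p-values over peaks or genes, which are not independent of each other, do not measure variation between animals.

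The highest peak lay at the start of IntS6, which encodes a subunit of the Integrator complex (FBgn0261383; X, 5746471 to 5747840). Its signal value of 15205 ranked first in all 3 replicates and compared with 6382 for the next peak, at the start of the sugar nucleotide transporter gene Ugalt (FBgn0024994, X, 2703651 to 2704108). The third peak (2L, 480571 to 481340) had a signal value of 6242 and lay in an intron of ush, 1373 bp from the start of cbt (FBgn0043364), a zinc-finger factor gene. CG14100 (FBgn0036889) had a promoter peak at 3L, 19590394 to 19590855, with signal 6043, and CG11050 (FBgn0031836) an intronic one at 2L, 6612454 to 6612936, with signal 5475. Peaks also lay at Chro, which encodes the interband protein Chromator (3L, 22878677 to 22879145, signal 4593), Trl, which encodes GAGA factor (intron, 3L, 14759283 to 14759759, signal 4352), and the Polycomb group gene ph-p (X, 2137119 to 2137610, signal 3957), 3 genes singled out after their values were seen. The others of the 20 highest peaks were nearest to px, PNPase, lncRNA:CR31840, mRpL41, Art3, Lk6, CG32772, HmgZ, Tcs5, CG1888, CG9663 and CG31145. Of the 20, 13 were promoter peaks and 7 lay in introns.

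Promoters held 2701 of the 6307 peaks (42.8%, 95% interval 41.6 to 44.1), against 13.6% for random placement, a ratio of 3.15. Of the pooled regions that overlapped no peak, 21.2% lay within 500 bp of a start. Part of the excess over random placement is therefore shared by regions outside the peaks. Summits at promoters lay mostly upstream: 2183 of 2701 (80.8%) were upstream of the nearest start, at a median position of -112 bp. The promoter share was 62.3% in the 631 peaks of highest signal (interval 58.4 to 66.1) and 34.6% in the 630 of lowest signal (30.9 to 38.5). Outside promoters, coding sequence held 16 peaks, or 0.254% of peaks against 13.7% of the genome. Introns held 39.4% of peaks against 39.5% of the genome, and intergenic sequence 15.0% against 27.2%. Summits over 1000 bp from any start numbered 2912 (46.2%). The excess at promoters had p = 1e-05 in the one-sided permutation test, the smallest the placements can give, and p = 1 for the opposite tail.

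**Figure D1:**
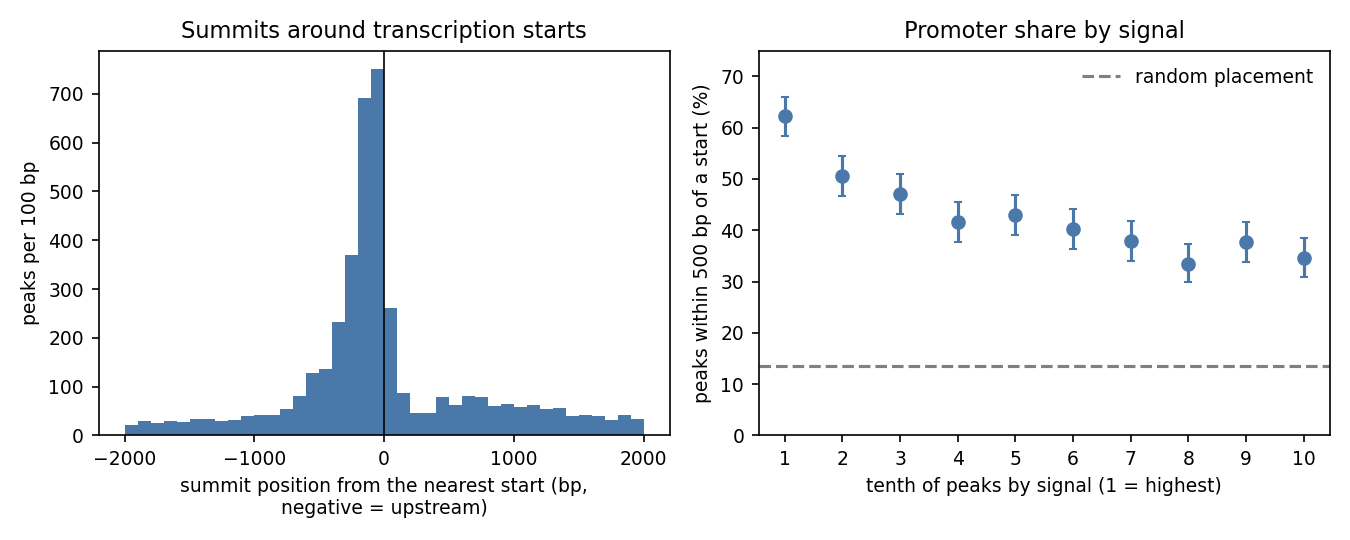
Left, number of IDR peaks per 100 bp by position of the summit from the nearest annotated start (bp, negative upstream). Right, percent of peaks within 500 bp of a start in 10 bins of signal value, with exact 95% intervals; the dashed line is the 13.6% given by random placement, and the share runs from 62.3% in the bin of highest signal to 34.6% in that of lowest.

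Chromosome arms 2L (1184 peaks, 50.4 per Mb) and 3L (1381 peaks, 49.3 per Mb) had more peaks than their length gives. The small heterochromatin-rich chromosome 4 had 17 peaks, 12.8 per Mb, and Y had 0. Y also had 0 of the 30000 regions of the pooled list and of each replicate list, so background regions are missing there as well. The ratio of chromosome 4 to its length was 0.278, and 0.129 without replicate 2 or 0.142 without replicate 3. X (47.9 per Mb), 2R (44.5 per Mb) and 3R (46.0 per Mb) did not pass the threshold, although 2R did without replicate 2 (ratio 0.926, adjusted p = 0.0218, exact). Adjusted p-values of the exact binomial tests were 0.00173 for 2L, 0.00709 for 3L, 1.26e-10 for chromosome 4 and 1.63e-68 for Y. When only X, 2L, 2R, 3L and 3R were compared, 0 arms passed, with ratios of 1.06 for 2L and 1.04 for 3L.

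Cytoplasmic ribosomal protein genes were bound most often: 70 of 86 (81.4%, interval 71.6 to 89.0) had a promoter peak, against 3004 of all 13968 coding genes (21.5%). RpL7 (signal 2284), RpS27 (2236), RpL23A (1615) and RpL34b (1466) had the highest signal values, and the median over the 70 genes was 662 against 420 over the 3004. Mitochondrial ribosomal protein genes had a promoter peak in 29 of 73 (39.7%), led by mRpL41 (signal 4149), mRpS10 (3904), mRpS23 (3510) and mRpL23 (2654). Genes of chromatin insulator proteins were bound in 10 of 19 cases (52.6%), among them Chro (4593), Cp190 (1947), M1BP (939) and Dref (858). Circadian clock genes were bound in 7 of 10 cases (70%), including sgg (1570), vri (701), cry (367) and dco (300.4). By Fisher's exact test the adjusted p-values were 5.35e-31, 0.00215, 0.00918 and 0.00523 in the same order. The mitochondrial ribosomal list did not pass the exact test with the 3153 peaks of highest signal (adjusted p = 0.349), without replicate 2 (0.194), without replicate 3 (0.275) or with peaks covered in all 3 replicates (0.256), and the insulator list did not pass without replicate 2 (0.0666). The clock list did not pass with a 250 bp window (0.206), with the 3153 peaks of highest signal (0.327), or against random lists matched on the number of starts per gene (0.0900 by permutation), a comparison chosen after seeing the data. Against lists matched on starts and on a divergent neighbour, also chosen after seeing the data, it passed (70% against 26.9%, adjusted p = 0.0166, permutation).

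Many promoter peaks lay near the starts of several genes. Of 80 named list members with a promoter peak, 43 had another gene's start within 500 bp of the summit, and for 18 that start was nearer, as for Dref (RpL13), M1BP (CG8202), mRpS23 (CenG1A) and mRpS10 (Art3). When each peak counted for the nearest start alone, 69 of 86 cytoplasmic ribosomal protein genes (80.2%) and 7 of 10 clock genes had one, against 15.8% and 16.1% of other coding genes. By this count 13 of 73 mitochondrial ribosomal protein genes had one (17.8% against 16.2% of others, odds ratio 1.16, adjusted p = 0.889, exact), as did 6 of 19 insulator protein genes (31.6% against 16.1%, odds ratio 2.50, adjusted p = 0.354, exact), and neither list passed. Of the 73 mitochondrial ribosomal protein genes, 53 had an opposite coding start up to 500 bp upstream, and against random lists matched on this and on the number of starts the list did not pass (39.7% against 30.3%, adjusted p = 0.234, permutation). These comparisons were chosen after seeing the data.

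Promoter peaks were fewer at receptor and cuticle protein genes than at other coding genes. Of 179 odorant, gustatory and ionotropic receptor genes, 1 had a promoter peak (Ir60e, signal 259, with the start of CG13585 nearer the summit), and of 117 cuticle protein genes, 2 did (Cpr67Fb, 253, and Cpr65Av, 214). None of the 111 replication-dependent histone genes, such as His1:CG31617 and His1:CG33801, had one, and 0 regions of any dm6 list lay in their cluster on 2L. Adjusted p-values were 1.03e-16 for the receptors, 2.56e-09 for cuticle proteins and 2.16e-11 for histones (Fisher's exact test).

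Embryonic patterning lists did not pass the threshold. Promoter peaks were present at 2 of 8 Hox genes (Dfd, signal 238, and Antp, 226) and 1 of 9 pair-rule genes (hry, 299.8). They were also present at 2 of 10 segment polarity genes (nkd, 813, and ptc, 219) and 2 of 16 dorsoventral genes (tin, 1130, and brk, 903). On the gap and head-gap list 1 of 12 members had one (bcd, 523), and bcd is a maternal gene rather than a gap gene. Neural fate genes had 3 of 16 (2131 at elav, 218 at pros, 205 at mira) and muscle genes 4 of 16 (962 at sls, 729 at mbc, 597 at htl, 245 at Mef2). Germline genes had 3 of 13 (418 at gcl, 411 at spn-E, 281 at vas), and Enhancer of split genes 3 of 7 (1665 at E(spl)m3-HLH, 943 at E(spl)m7-HLH, 689 at E(spl)mdelta-HLH). Adjusted p-values in these 9 lists were 0.402 or more by Fisher's exact test.

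Among regulatory and housekeeping lists, 7 more did not pass. Polycomb group genes had a promoter peak in 7 of 17 cases, with signal values of 3957 at ph-p, 1678 at E(z), 371 at ph-d and 322 at Psc (adjusted p = 0.178, Fisher's exact test). Heat shock genes had one in 8 of 19 cases, with 1939 at Hsp27, 1425 at Hsp83, 972 at Hsc70-5 and 638 at Hsp26 (adjusted p = 0.129, exact). Both lists passed the exact test, each with adjusted p = 0.0204, when genes with starts within 500 bp of each other were counted as 1 and a peak at any of their starts counted. Heat shock genes also passed without replicate 1 (adjusted p = 0.0331, exact) and with each peak counted for the nearest start alone (adjusted p = 0.0249, exact). Ecdysone response genes had 4 of 13 (2712 at E23, 1134 at Eip75B, 866 at Hr78, 458 at usp), DNA replication genes 7 of 22 (1139 at RnrS, 979 at CycE, 796 at dpa, 557 at Mcm2) and splicing genes 5 of 19 (1149.7 at U2af50, 510.5 at Prp31, 466 at SmD3, 442 at B52). Oxidative phosphorylation genes had 22 of 87 (1044 at ND-ASHI, 932 at blw, 905 at ND-MWFE, 647 at ND-42) and proteasome genes 8 of 32 (767 at Rpn3, 571 at Rpn5, 469 at Rpn13, 385 at Rpn11).

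RNA genes were counted without the planned test. Promoter peaks were present at 17 of 290 tRNA genes (tRNA:Tyr-GTA-1-8, 1870), 23 of 253 snoRNA genes (snoRNA:Or-CD11a, 1351) and 8 of 32 snRNA genes (539 at snRNA:U1:95Ca, 489 at snRNA:U5:63BC). Neither of the named snRNA peaks overlapped any of the 30000 regions of replicate 1. The tRNA:Tyr-GTA-1-8 peak also lay within 500 bp of the start of CG8036, and the snoRNA:Or-CD11a peak within 500 bp of those of RpL28 and eIF1, both nearer its summit. With each peak counted for the nearest start alone, 7 tRNA, 7 snoRNA and 7 snRNA genes had one. Against all other genes that are not protein coding, a background chosen after seeing the data, the snRNA list, which also holds 7SK, had adjusted p = 0.00645 by Fisher's exact test, 25% against 7.48%. The tRNA and snoRNA lists, counted there over all biotypes (17 of 295 and 24 of 257), did not pass (adjusted p = 0.275 in each, exact).

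**Figure D2:**
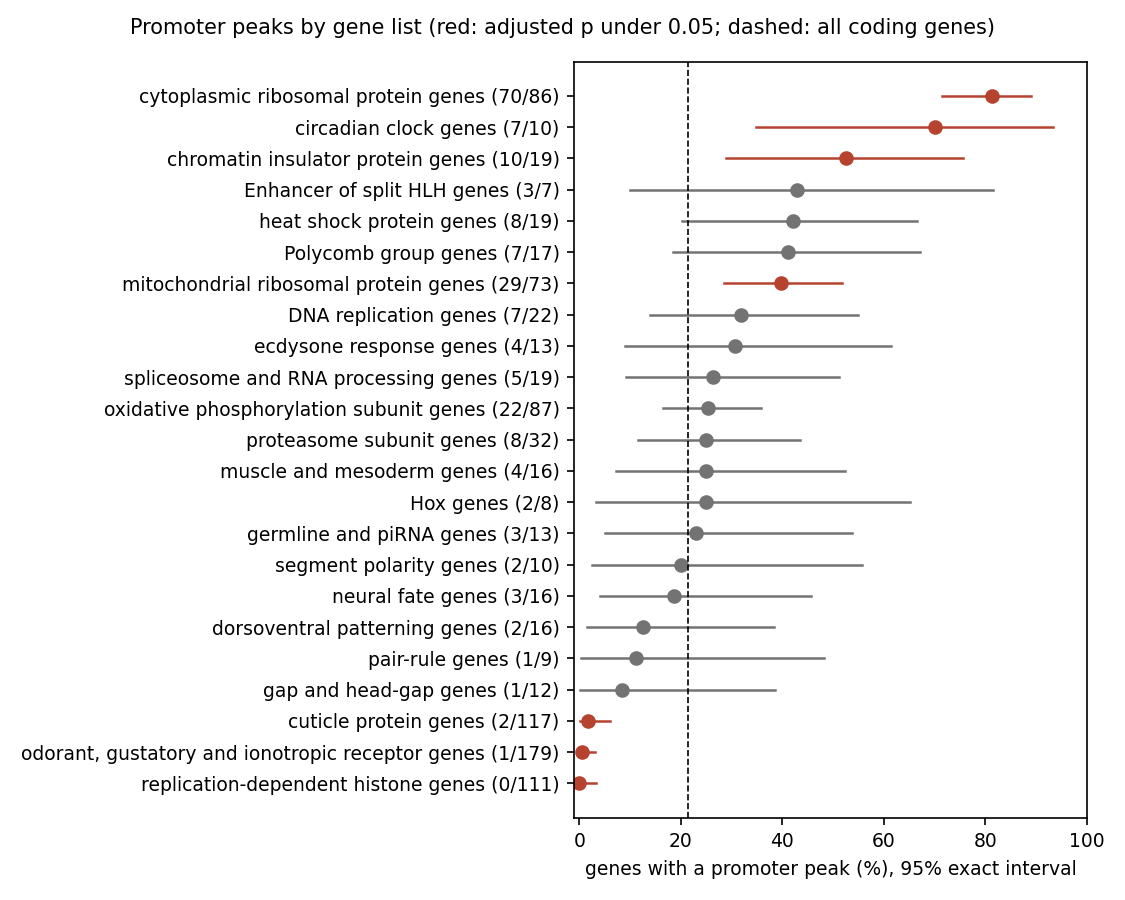
Percent of genes with a promoter peak in each of the 23 lists tested, with exact 95% intervals and the numbers of bound and annotated members; red marks adjusted p under 0.05 and the dashed line all coding genes (21.5%). Cytoplasmic ribosomal protein genes lie highest at 81.4% and histone genes lowest at 0.

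CG10209 itself (FBgn0033971, 2R, 14846064 to 14848366, minus strand) had a promoter peak at 14848104 to 14848569, with a signal value of 2040, rank 116 of 6307. The region ranked 226 in replicate 1, 46 in replicate 2 and 121 in replicate 3. Within 20 kb of the gene lay 3 peaks against 1.95 given by length, the others at 14852630 to 14852890 and 14855203 to 14855495. The files do not separate the endogenous gene from the tagged copy.

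Of 18 motifs, 10 were more frequent at summits than in flanks and 5 less frequent. The DNA replication-related element (DRE, TATCGATA) was found at 2.54% of summits and 0.555% of flanks, core promoter motif 1 at 1.27% and 0.190%, motif 7 at 4.57% and 2.00%, and the CTCF consensus at 1.65% and 0.381%. Homeodomain sites (17.7% against 12.7%), the TATA box (4.87% against 3.23%), motifs 5 and 6, Su(Hw) and GATA were also higher. Sites for Pho (3.52% against 5.28%), Twist or Snail (7.52% against 9.70%), Bicoid, GAGA factor and the DPE were lower at summits, while Initiator, Zelda and ETS sites did not pass the threshold. Summits held more A and T than flanks (64.3% against 57.8% of bases in even-ranked peaks), and these tests do not correct for base composition. Exact McNemar tests gave adjusted p-values of 4.86e-19 for DRE, 7.72e-13 for motif 1, 5.89e-15 for motif 7 and 1.65e-12 for CTCF. The promoter motifs depended on the comparison: among the 2912 peaks over 1000 bp from a start, a subset chosen after seeing the data, DRE was at 0.343% of summits and 0.378% of flanks, and motif 7 at 1.65% and 1.82%, whereas CTCF had 1.58% against 0.343% (adjusted p = 2.24e-05, exact). Promoter summits had DRE less often (5.41%) than windows centred on the starts of unbound promoters (6.82%). A further comparison, also chosen after seeing the data, centred windows in both sets on the start of lowest coordinate of each coding gene. For bound genes that start need not be the one with the peak, so the windows can miss the peak. DRE was at 9.05% for bound and 6.82% for unbound genes, motif 7 at 12.5% and 5.58%, TATA at 3.76% and 9.11%, and CTCF at 0.786% and 0.443% (adjusted p = 0.0555, exact). In that comparison GAGA sites passed in the opposite direction, at 5.23% for bound and 3.36% for unbound genes (adjusted p = 1.53e-05, exact). Initiator was at 23.6% and 31.6% (adjusted p = 1.38e-16, exact), and homeodomain sites did not pass, at 9.80% and 9.62% (adjusted p = 0.824, exact). Promoter summits against starts of unbound promoters gave Initiator at 16.8% and 31.6% (adjusted p = 1.51e-54, exact) and ETS at 0.555% and 0.184% (adjusted p = 0.00448, exact). Promoter summits lay at a median of -112 bp from the start, so their windows can miss an element at the start itself. The Initiator difference at summits cannot be separated from this offset. In the same comparison homeodomain sites passed, at 18.3% and 9.62% (adjusted p = 1.04e-32, exact), as did CTCF, at 1.70% and 0.443% (adjusted p = 1.03e-09, exact). Of 11 alternatives, the calls for GATA and motif 6 held in 2, those for DPE and Su(Hw) in 4 and that for Bicoid in 6.

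**Figure D3:**
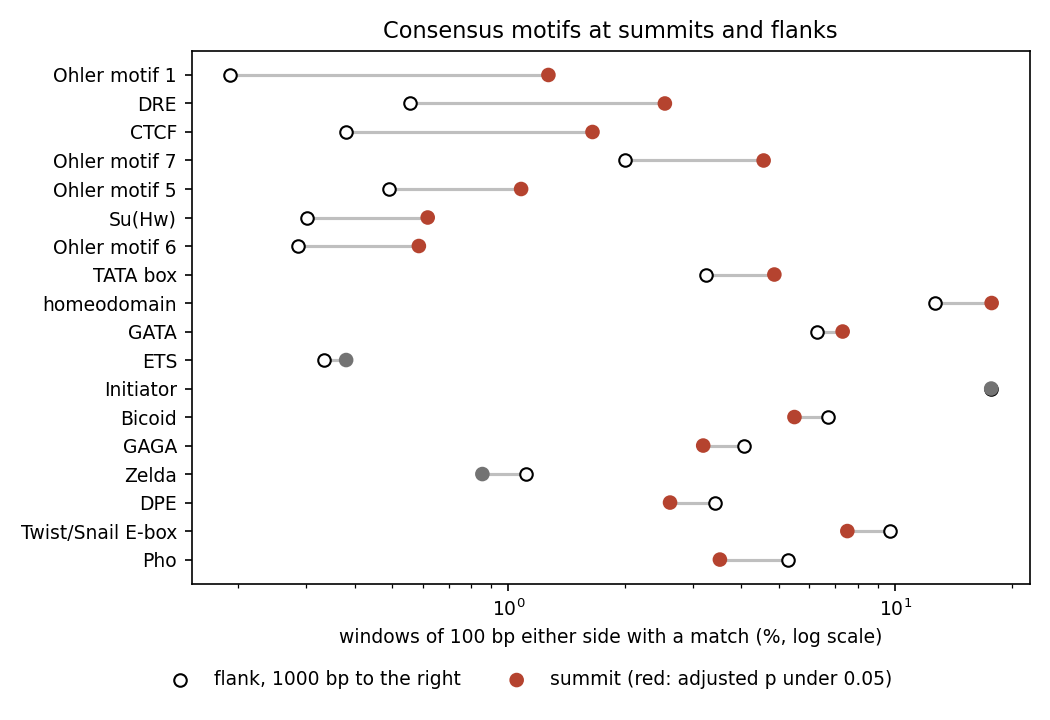
Percent of 6307 IDR peaks with a match to each of 18 consensus motifs within 100 bp of the summit (filled) and in the window 1000 bp to its right (open), on a log scale; red marks adjusted p under 0.05. Motif 1, DRE and CTCF show the widest separation, for example 2.54% against 0.555% for DRE.

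Words of 8 bases were compared without a preset motif. CACTGAGA occurred at 120 of 3153 tested summits (3.81%) and 17 flanks (0.539%), TACACTGA at 93 and 21, and CACTGTGC at 120 and 41. TACACTGA ends in CACTGA, with which CACTGAGA begins, so these words need not be separate signals. Over all 6307 peaks, CACTGAGA had 27 and 24 matches in the 40 bp bins next to the summit. It had 58 to 69 in each bin from 40 to 120 bp on either side. CACTGTGC had 26 and 34 next to the summit and 60 to 81 in those bins, so both words lay more often beside the summit than at it. The other 7 of the 10 best words held only A and T, for example TTTAAAAA at 321 summits and 137 flanks. Some of these overlap each other too, such as TTTAAAAA and TTAAAAAA. All 10 passed in the tested peaks, with adjusted p = 2.81e-19 for CACTGAGA and 5.45e-19 for TTTAAAAA (exact McNemar tests). TTTAAAAA was again among the best 10 in all 7 other settings with 8-base words, CACTGAGA in 6, the exception being the 3153 peaks of highest signal, and AAAAATAT in 5. The other 7 words, TACACTGA and CACTGTGC among them, recurred in 1 or 2 of the 7, and 3 to 6 of the 10 words were shared with each of these settings.

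Replicates shared most peaks where an overlap of 1 bp sufficed, and fewer under the stricter overlaps given further below. The top 6307 regions covered 82.3% of the IDR peaks in replicate 1, 83.4% in replicate 2 and 90.9% in replicate 3, a mean of 85.5% ± 4.66 (SD, n = 3), and 4162 peaks (66.0%) were covered in all 3. Peaks placed at random were covered in all 3 in 1.98% of cases, at most 2.55% in 100 placements. All 30000 regions overlapped 89.3% of the peaks in replicate 1, 98.9% in replicate 2 and 99.7% in replicate 3. Promoter peaks without a region in replicate 1 include those named for Dref, U2af50, SmD3, Rpn3, Rpn13, ND-42, Psc, pros, vas and Ir60e. The peak named for Dfd had no region in replicate 2. Spearman's correlation of signal values over peaks was 0.755 between replicates 1 and 2, 0.847 between 1 and 3 and 0.838 between 2 and 3. Because the IDR peaks were chosen from these replicates, the overlap is not an independent measure of agreement.

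**Figure D4:**
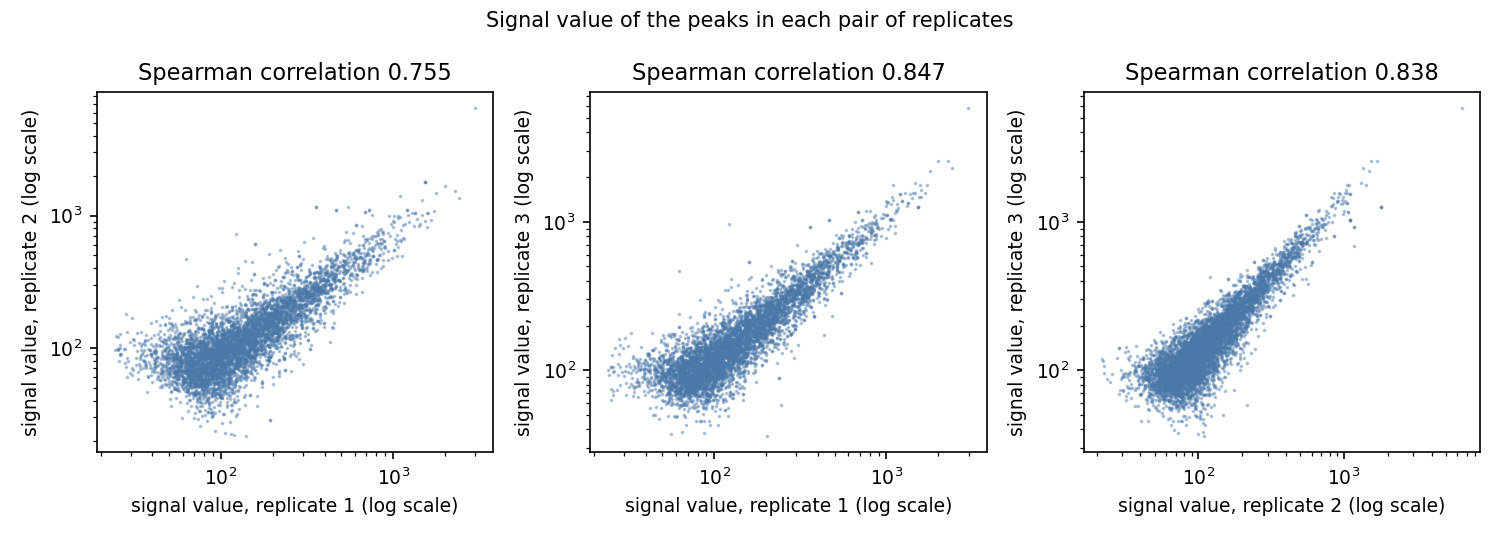
Signal value of the IDR peaks in each pair of replicates, both axes on a log scale, 1 point per peak found in both lists. Spearman's correlation coefficients are 0.755, 0.847 and 0.838.

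The dm3 files held 5864 IDR peaks, 93.0% of the number in dm6, with 1043 against 1125 on X and 13 against 17 on chromosome 4. Of the 20 highest dm6 peaks, 20 had a peak on the same arm within 1% of their signal value among the 40 highest dm3 peaks. No test was made between builds.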

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

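The regions in this part were looked at after the peaks had been described. The pooled list held 1443 regions with a −log10 q of 2 or more that overlapped no IDR peak. They drew attention as signal outside the peaks that the comparisons use. Of these, 447 (31.0%) lay within 500 bp of a start, between the 13.6% of random placement and the 42.8% of the peaks. Over all 22351 pooled regions that overlapped no peak, 21.2% did. Regions with a −log10 q of 2 or more in all 3 replicates overlapped 5 of them, and 110 overlapped none in any replicate. Their signal values reached 194.667, just under the 194.682 of the lowest peak, and had a median of 176, so that such regions remain follows from where the peak list ends. No cause was tested. No search for outlying replicates was made, and there is no second group to compare. Replicate 1 had 4296 regions at a −log10 q of 2 or more, against 9183 and 9015 in the others.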

How the results depend on the processing

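Alternatives comparing starts of bound with starts of other genes, peaks over 1000 bp from a start, peaks covered in all 3 replicates, lists matched on starts or also on a divergent neighbour, peaks counted for the nearest start and the other background for RNA genes were chosen after seeing the data. Promoter share was above random placement in all settings, from 32.1% against 7.51% with a 250 bp window (ratio 4.28) to 53.8% against 23.7% with 1000 bp (ratio 2.27), each with the smallest p the placements can give. Cytoplasmic ribosomal, receptor and cuticle lists kept their calls in all 13 settings. For histone genes the settings say nothing, as no list has a region in their cluster. Lists past the threshold numbered 5 to 9, motifs 6 to 15. Motifs fell to 8 for starts of bound genes and to 6 for peaks over 1000 bp from a start, and the cause was not tested. The count of arms went from 4 to 0 with X, 2L, 2R, 3L and 3R alone. Chromosome 4 and Y leave that test, and 2L and 3L no longer passed (adjusted p of 0.0737 and 0.203, exact). Overlap in all replicates was 47.5% with 50% reciprocal overlap, 58.1% with summits within 100 bp, 37.7% with the top N/2 regions, 85.7% with the top 2N, and 69.1 to 78.1% when a replicate was left out. Spearman's correlation was 0.755 to 0.847 when a replicate was left out, 0.755 without replicate 3. Above the median signal of the dm6 list, dm3 held 98.0% as many peaks.

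Motif ratios changed direction as follows. Summit to flank ratios divide the peaks with a match at the summit alone by those with a match in the flank alone. Against promoters without a peak, the odds ratios of promoter peaks against these promoters were 0.782 for DRE, 0.687 for motif 1, 0.852 for motif 5, 0.728 for motif 6, 0.576 for TATA, 1.09 for GAGA, 1.16 for Twist or Snail and 0.904 for GATA. These windows are centred on summits for peaks and on starts for the other promoters. With the start of lowest coordinate of each gene in both sets, the odds ratios of bound against unbound genes were 0.391 for TATA, 1.07 for DPE, 1.59 for GAGA and 0.840 for GATA. Over 1000 bp from a start, summit to flank ratios were 0.913 for DRE, 0.448 for motif 5, 0.765 for motif 6 and 0.905 for motif 7. Bicoid gave a summit to flank ratio of 1.01 with 50 bp windows, and ETS 0.946 without replicate 3 and in peaks shared by all replicates. Where the construction of an alternative does not show it, the cause was not tested. Of 23 lists, 14 passed in no setting, as did 1 of 18 motifs and 2 of 7 arms. Single lists, motifs and arms that passed in no setting were left out of the comparison of directions, a choice made after seeing the data. Over the others, 250 values kept direction and side of the threshold, 55 no longer passed, 8 newly passed and 19 reversed. Alternatives needing a dm3 genome were not run. Read depth is unknown, so its effect on replicate 1, with the fewest regions at a −log10 q of 2, cannot be separated.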

Other observations

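The gene sets and tests in this part were chosen after the peaks were seen, except that the tests of abundant transcripts, word composition, word position and the histone cluster had their outcomes stated before they were run. Integrator genes had a promoter peak in 5 of 11 (signal 15205 at IntS6, 627 at IntS11), translation elongation factors in 4 of 8 (1482 at eEF1gamma, 663 at eEF1alpha1) and Mediator genes in 8 of 25 (1053 at MED30, 1029 at MED17). Initiation factors had 13 of 44 (3045 at eIF4EHP, 2714 at eIF6), aminoacyl-tRNA synthetases 10 of 32 (1000.4 at SerRS, 993 at IleRS) and TBP-associated factors 4 of 15 (773 at Taf5, 736 at Taf4). None of these 6 families passed Fisher's exact test after adjustment (lowest adjusted p = 0.213; 0 of 6 had an unadjusted p under 0.05).

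Binding of all ubiquitously active promoters alike would give proteasome, oxidative phosphorylation and splicing genes the 81.4% seen at ribosomal protein genes, but they had 35 of 138 (25.4%, Fisher's exact p = 1.44e-16). Number of starts does not account for it either, as the highest of 10000 lists matched on starts reached 34.9%. Very high transcription may contribute: of 25 other genes with abundant transcripts by general knowledge, 60% had a promoter peak (interval 38.7 to 78.9), above other coding genes (21.1%, exact p = 2.67e-05) and below ribosomal protein genes (exact p = 0.0339). The lower share had been set beforehand to count against it, but this was set aside after the result was seen, because it assumes transcription as strong as that of ribosomal protein genes, which no value here shows. Very high transcription therefore stays open, as does signal from any tagged protein, and with 1 group no biological explanation that rests on a comparison of groups was tested for this or the following patterns.

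For the AT-only words at summits, base composition is a candidate explanation: 136 of 136 such 8-base words (100%) were more frequent at the centre, where 64.3% of bases were A or T against 57.8% in flanks, and the homeodomain consensus TAATTA also holds only A and T. Composition does not account for CACTGAGA, whose ratio lay at percentile 99.982 of 5559 words with as many G and C. Nor do nearby annotated starts account for it, since in peaks over 1000 bp from any annotated start it was at 82 summits and 13 flanks (exact McNemar p = 2.08e-13). What binds CACTGAGA was not tested, and unannotated starts and repeats were not examined.

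The absence of peaks at histone genes may be technical. Their cluster (2L, 21416953 to 21541681) held 0 of the 30000 pooled regions against 27.3 given by length (exact binomial p = 2.26e-12), and 0 in each replicate list. Background regions are missing there as well, which is consistent with repeated copies that leave few uniquely placed reads. Binding at histone genes therefore stays open, and how the authors treated reads with several positions is not given in the sources used here.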
